A study of Homo sapiens with 2 samples.

How the data were processed

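RNA sequencing compared 1 library of parental Capan-1 cells with 1 library of a derivative made resistant to olaparib. Per the labels, resistance was obtained by stepwise exposure to olaparib from 15 nM to 128 uM, and total RNA was isolated with Trizol and made into strand-specific ScriptSeq libraries. Capan-1 is an established pancreatic adenocarcinoma line with a mutant BRCA2 gene, while the labels' cell type field reads breast cancer. The columns headed with the parental line's name were taken as parental. The other pair of columns, whose heading is not spelled out in the labels, was taken as resistant because it was the remaining library, and every direction below rests on that assignment.

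The deposited table lists 31845 Ensembl genes with a count and an FPKM value per library, per the file headers. The counts as deposited are whole numbers with no normalization, and no gene is at 0 in both libraries. The FPKM values were computed by the authors with 1 length per gene, per the file headers and the values themselves. The ratio of the FPKM denominators of the resistant and the parental library was 0.959 over 2584 genes, while the ratio of their count totals was 0.998. RSEM 1.2.3 and the build hg19 are named per the submitters' processing notes, which give neither a role. Whether the counts are rounded estimates, which annotation was used and whether counting used strand are not given in the sources used here. Genes that overlap another gene, and genes with near-identical copies, are therefore uncertain.

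Symbols were taken from a gene name table, which matched 29536 identifiers, and from GENCODE release 29, which matched 29719. The 2126 identifiers left unnamed held 7.03% of the counts of the resistant library and 8.90% of those of the parental library. GENCODE describes another build than the one named for the files, so no coordinates are given. It served only for names, gene types, gene order, exonic length, genomic span and GC content. Gene length elsewhere was the count over the FPKM value, a relative length, and not a GENCODE length.

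Totals were 34572931 counts in the parental library and 34507480 in the resistant library. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, and log2 ratios of resistant over parental used a prior of 1 count. A gene was counted as higher or lower when it had at least 50 counts in the higher library and differed at least 2-fold. With 1 library per group there is no replicate, so no test between the groups was run and no p-value is given, and every difference describes these 2 libraries. Intervals of ratios are exact conditional (Clopper-Pearson) 95% intervals and cover counting error only. Against a library at 0, a fold is a lower bound computed with a floor of 3 counts per library, the same floor on every scale.

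Protein-coding genes at 50 counts or more were placed in gene order. Medians were taken in running windows of 21 genes. Each chromosome was divided by penalised least squares on the same log2 ratios into segments of at least 5 genes. Counts of changed genes within a segment therefore follow in part from how its ends were chosen. The highest window was compared with 1000 random gene orders. The median of each gene list, over members at 50 counts or more, was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with under 3 such members have no median. Percentiles describe these libraries and are not tests.

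The gene lists, the settings and the rule for named genes were fixed before the data were examined, except for 2 intestinal lists written afterwards. The rule named BRCA2, then every listed neighbour at 50 counts or more. It added the 10 highest and 10 lowest log2 ratios among genes with at least 200 counts in a library, leaving out clone names, pseudogenes and small RNAs whose symbols start with MIR, SNOR, SCARNA, RNU, RNY or RN7S. RNVU1-17, a small RNA with another prefix, was not left out. From each list it took up to 4 members past 2-fold with the largest differences, or the 2 largest where none passed. A gene that the rule named and a chromosome segment are not reported here. Other genes, among them CDX2, VIL1 and further genes of the chromosome 13 block, were chosen after their values were seen.

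Alternatives covered scaling by the median of ratios, the upper quartile or the total, the total without histone and ribosomal protein genes, other prior counts, other count minimums, a larger fold size, a required counting interval, and means in place of medians. The deposited FPKM values, removal of the trend with gene length, protein-coding genes alone and omission of chromosome 13 were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

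The calculations were tested on simulated data for the same comparison, scaled by library totals, with 14599 genes at the count minimum. All 50 genes at each of a 3-fold and an 8-fold difference in either direction were recovered, and 1 of 14362 unchanged genes was called. The 95% intervals held the true ratio for 95.3% of genes. Both simulated libraries were Poisson counts around shared means, apart from the planted differences. They held no variation between cultures or libraries, so these rates cover counting error only. A planted 40-gene block was recovered with 40 of its 40 genes among 636 genes in shuffled order. Of 400 random 25-gene lists, 16 fell outside the 2.5 to 97.5 percentiles.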

Results

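Transcript levels were measured by RNA sequencing in 2 libraries, 1 of parental Capan-1 cells and 1 of an olaparib-resistant derivative. Capan-1 is a pancreatic cancer line with a mutant BRCA2 gene, and olaparib inhibits PARP enzymes, on which cells lacking homologous recombination depend. The parental library held 34572931 counts over 28834 genes and the resistant library 34507480 over 27940 genes. There was no replicate. The comparison asks how the resistant line differs from its parent, with the level of BRCA2 first, since the series title names amplification of the mutant gene.

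BRCA2 had 7585 counts in the resistant library and 1381 in the parental library, a 5.53-fold higher level (counting interval 5.22 to 5.86) and a log2 ratio of 2.47. The deposited FPKM values of BRCA2 were 44.3 and 7.74. Its log2 ratio exceeded that of 99.0% of the 15102 genes with at least 50 counts. The listed neighbours of BRCA2 were also higher. N4BP2L1 was 8.93-fold higher, RFC3, a clamp loader subunit, 5.89-fold, N4BP2L2 5.46-fold and STARD13 4.63-fold. HSPH1 was 3.56-fold higher, PDS5B, a cohesin regulator, 3.43-fold, FRY 3.42-fold, B3GLCT 3.32-fold and USPL1 3.28-fold. NBEA was 1.65-fold higher and the pseudogene EEF1DP3, which overlaps FRY, 1.43-fold. The 11 neighbours at the count minimum had a median log2 ratio of 1.78, at the 100th percentile of matched random lists, and 9 were at least 2-fold higher.

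In gene order, BRCA2 lay inside a run of 40 protein-coding genes from MTMR6 to SUPT20H with a median log2 ratio of 2.29, or 4.89-fold. Of these genes, 39 were at least 2-fold higher and 27 at least 4-fold higher, from NBEA at 0.73 to N4BP2L1 at 3.14, and BRCA2 ranked 10. The ends of the run were set from these same ratios, which raises such counts. The run also held CDX2, an intestinal transcription factor, at 2.85, EXOSC8, an exosome subunit, at 2.86, NUP58 at 2.71, GTF3A at 2.69, POMP, a proteasome assembly factor, at 2.59 and HMGB1 at 1.87. The 10 measured coding genes on each side of BRCA2 had a median of 2.29, and 19 of these 20 were at least 2-fold higher. SOHLH2 and CCDC169-SOHLH2, which overlap, had identical counts and may share the same reads, and each of these numbers includes both.

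The rest of chromosome 13 differed from this block. The 26 genes before it, from MPHOSPH8 to PABPC3, had a median log2 ratio of 0.83. Of these, 11 were at least 2-fold higher and 24 had a log2 ratio above 0. The next 67 genes, starting at UFM1, had a median of -0.85, and 25 of them were at least 2-fold lower. MZT1 to SPRY2 had a median of 0.39 over 20 genes, and SLITRK6 to CHAMP1 one of -0.68 over 57 genes. The highest 21-gene median in the block was 2.31. The highest on any other chromosome was 0.92, around RAN on chromosome 12.

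**Figure D1:**
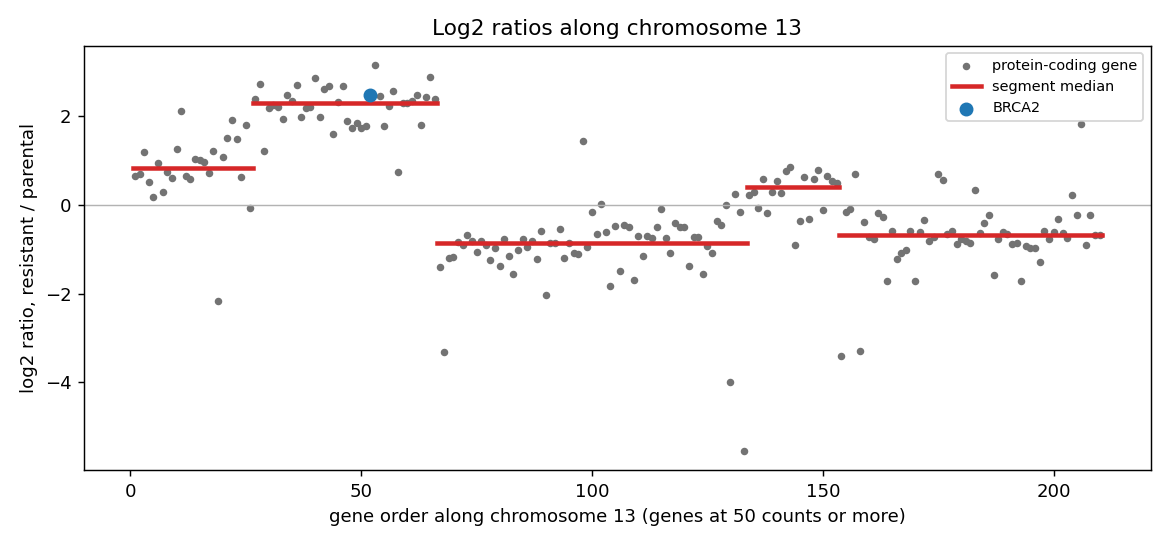
Log2 ratios of resistant over parental for protein-coding genes at 50 counts or more in gene order along chromosome 13, with segment medians as red lines and BRCA2 in blue. The 40-gene segment holding BRCA2 has a median of 2.29 and the segment after it one of -0.85.

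**Figure D2:**
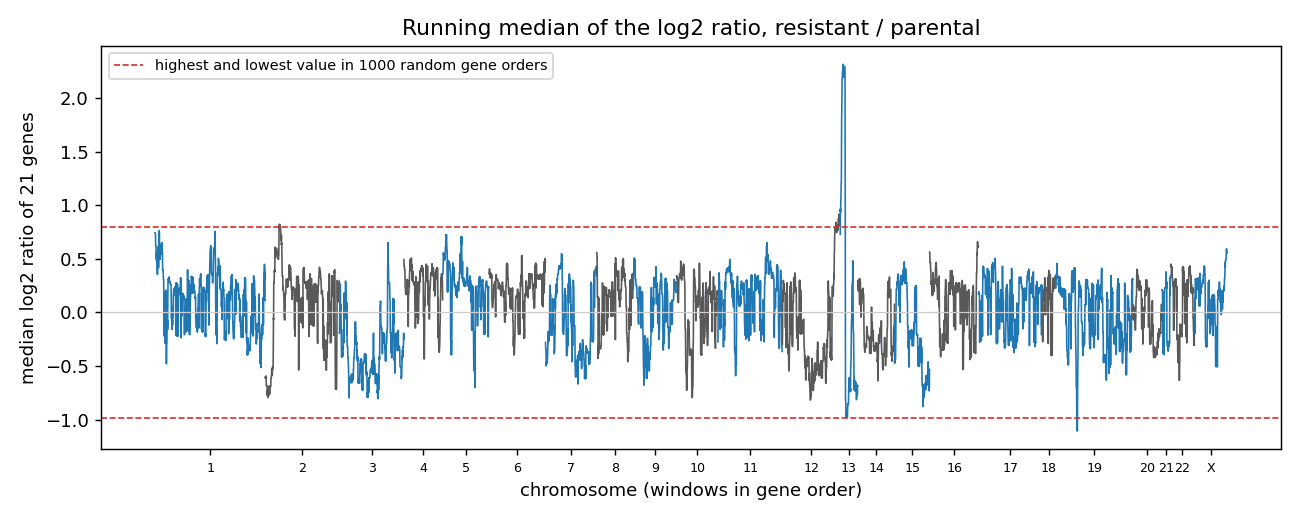
Median log2 ratio of resistant over parental in running windows of 21 genes along each chromosome, with dashed lines at the highest and lowest values of 1000 random gene orders. The chromosome 13 block reaches 2.31, and the highest value on any other chromosome is 0.92.

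Across the transcriptome, 906 genes were at least 2-fold higher in the resistant library and 1352 at least 2-fold lower, among the 15102 genes at the count minimum. At 4-fold, 252 were higher and 250 lower. The other 12844 genes (85.0%) lay within 2-fold. The counting interval excluded equal levels for 84.9% of genes, so depth did not limit most ratios.

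Among the 10 highest ratios, NTS, which encodes neurotensin, had 478 counts in the resistant library and 0 in the parental library, at least 160-fold higher. HEPH, an intestinal ferroxidase, had 292 and 0 counts, at least 98.0-fold higher. BCHE had 687 and 3 counts, a ratio of 231 (interval 78.5 to 1121), and ST6GALNAC5 had 231 and 1, a ratio of 233 (interval 41.3 to 9224). ADAMTS12, a secreted protease, was 136-fold higher, the non-coding LINC01322 116-fold, the intestinal annexin ANXA13 102-fold and FREM1 96.4-fold. SI, sucrase-isomaltase, had 330 and 3 counts, a ratio of 111 (interval 37.6 to 540). RNVU1-17 had 819 and 0 counts, at least 275-fold higher, but this U1 RNA variant has near-identical copies and its value is uncertain.

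At the other end, DOK5, a signalling adaptor, had 0 counts in the resistant library and 527 in the parental one, at least 175-fold lower. The potassium channel gene KCNQ3 had 3 and 488 counts, a ratio of 162 in favour of the parental library (ratio of resistant over parental 0.00619, interval 0.00127 to 0.0182). BPIFB1, a secreted airway and gastric protein, was 93.3-fold lower, ANKFN1 80.1-fold, PDE7B 42.2-fold, WSCD2 39.7-fold and LINC02015 28.9-fold. SYNE1 was 21.6-fold lower, and CALB1, calbindin, had 207 resistant and 3953 parental counts. LYZ, lysozyme, had 1555 resistant and 30464 parental counts, 19.5-fold lower.

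Homologous recombination genes were slightly higher as a group in the resistant library, with a median log2 ratio of 0.43 over 36 genes at percentile 99.95. BRCA2 was the 1 member past 2-fold. Fanconi anaemia genes had a median of 0.32 over 24 genes (percentile 94.4), with CENPS at 0.69, which overlaps CENPS-CORT, and WDR48 at -0.65. End joining and end protection genes had a median of 0.27 over 25 genes (percentile 84.2). In that list SHLD1, a shieldin subunit, was 4.16-fold higher with 62 and 15 counts, and RIF1 2.25-fold higher with 67 and 30 counts. XRCC4 was 2.25-fold higher, while TP53BP1, which acts upstream of shieldin, was 2.07-fold lower. TP53BP1 overlaps TUBGCP4, and XRCC4 overlaps TMEM167A.

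PARP and single-strand break repair genes had a median of 0.16 over 29 genes (percentile 68.6), all within 2-fold, with the glycosylase genes NTHL1 at 0.93 and OGG1 at 0.80. PARP1, the main target of olaparib, had 392 resistant and 423 parental counts. Fork protection and PARP inhibitor response genes had a median of 0.18 over 25 genes (percentile 63.4), with TIPIN 2.73-fold and ZRANB3 2.48-fold higher. DNA damage checkpoint genes had a median of 0.18 over 25 genes (percentile 64.7), led by RAD1 at 1.00 and ETAA1 at 0.79. ABC transporter genes went both ways, with 4 higher and 4 lower of 17 and a median of 0.43 (percentile 95.4). ABCA7 was 2.75-fold, ABCC10 2.53-fold and ABCA5 2.49-fold higher, and ABCC11 3.97-fold lower with 14 resistant and 56 parental counts. ABCB1, which encodes the drug pump that exports olaparib, had 10 resistant and 4 parental counts, too few to compare.

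DNA replication genes had a median log2 ratio of 0.42 over 34 genes (percentile 99.97), with POLE at 0.97 and MCM4 at 0.89. None of the listed genes was past 2-fold, but the list leaves out the clamp loader gene RFC3, which was 5.89-fold higher. G2/M genes had a median of 0.29 over 30 genes (percentile 88.7), with AURKB at 0.76 and BUB1B at 0.70. With the trend with gene length removed, the G2/M median was 0.21 (percentile 57.6). Cholesterol synthesis genes had a median of 0.57 over 25 genes (percentile 100), with STARD4, a sterol carrier, 3.03-fold and MVD 2.14-fold higher. Oxidative phosphorylation genes had a median of 0.30 over 32 genes (percentile 92.9), with SDHD at 0.78 and SDHA at 0.69. Their median was 0.20 (percentile 52.1) with that trend removed. Hypoxia and glycolysis genes had a median of 0.35 over 24 genes (percentile 97.0), although VEGFA had a log2 ratio of -1.14 and EGLN3 one of -1.06. Ribosomal protein genes had a median of 0.15 over the 46 listed genes (percentile 20.3), from RPS7 at -0.59 to RPL7 at 0.60. The list leaves out RPL21, a gene of the chromosome 13 block with a log2 ratio of 2.46. Housekeeping genes had a median of 0.22 over 18 genes (percentile 63.2), with YWHAZ at 0.72.

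Inflammatory and growth factor genes were lower as groups. Interferon-stimulated genes had a median of -0.43 over 38 genes (percentile 0.03), with IFI44L 3.08-fold, OAS2 2.77-fold, HERC5 2.61-fold and RSAD2 2.11-fold lower. NF-kB cytokine and chemokine genes had a median of -0.56 over 19 genes (percentile 0.425), with CXCL5 3.18-fold and LIF 2.19-fold lower but CSF2 7.17-fold and IL1A 2.12-fold higher. Growth factor signalling genes had a median of -0.58 over 26 genes (percentile 0), with IGF1R 2.43-fold lower and FGFR4 2.07-fold higher. Once the trend with gene length was removed, their median was -0.30 (percentile 0.89). By that measure 0 of the 26, IGF1R included, were at least 2-fold lower. Antigen presentation genes had a median of 0.47 over 21 genes (percentile 99.35), with CD274, which encodes PD-L1, 3.33-fold and HLA-DPB1 2.28-fold higher, and HLA-DMA 7.25-fold and HLA-DRB1 2.52-fold lower. HLA genes share reads with close paralogs.

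Wnt, Notch and Hedgehog genes had a median of -0.49 over 16 genes (percentile 1.91), which moved to percentile 13.6 once the trend with gene length was removed. The Wnt target genes AXIN2 and LGR5 were 6.36-fold and 5.65-fold lower, PTCH1 2.79-fold and DLL1 2.52-fold lower. NRF2 and detoxification genes had a median of -0.29 over 30 genes (percentile 1.42), with ALDH3A1 6.68-fold, CYP2S1 3.24-fold and ALDH1A1 3.02-fold lower and ME1 2.84-fold higher. Unfolded protein response genes had a median of -0.24 over 23 genes (percentile 5.90), with ASNS 2.23-fold lower. Targets of p53 had a median of -0.30 over 26 genes (percentile 9.07). SPATA18 had 3 and 56 counts, a ratio of 0.0539 (interval 0.0108 to 0.166), PHLDA3 was 3.35-fold and TP53INP1 2.15-fold lower, and FAS 2.42-fold higher. Apoptosis genes had a median of 0.15 and a mean of -0.06 over 22 genes (percentile 56.7), with HRK 3.26-fold, CFLAR 2.06-fold and BBC3 2.06-fold lower.

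Genes of the classical pancreatic subtype diverged, with 8 higher and 8 lower of 28. CDH17, an intestinal cadherin, was 72.7-fold higher, REG4 31.7-fold and KRT20 17.3-fold, while LYZ was lower. The list's median was -0.36 (percentile 0.26) and its mean 0.16, so the 2 summaries differ in sign. Basal-like subtype genes had a median of -0.06 over 16 genes (percentile 40.7), which became 0.01 under upper quartile scaling. CTSV was 4.39-fold and VGLL1 2.73-fold lower, and DHRS9 5.69-fold lower with 11 resistant and 63 parental counts. Epithelial genes had a median of 0.20 over 29 genes (percentile 66.6), with DSC2 2.06-fold higher and CLDN18 3.24-fold and MUC1 2.54-fold lower. Mesenchymal genes had a median of -0.22 and a mean of 0.16 over 11 genes (percentile 28.99), with CDH2 5.16-fold, TGFBI 3.80-fold and AXL 2.65-fold higher and ITGA5 5.23-fold lower.

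Pancreatic duct genes had a median of -0.23 over 12 genes (percentile 11.2), with CA2 4.89-fold and CFTR 3.47-fold lower and MSLN, mesothelin, 11.6-fold higher. Mammary luminal genes had a median of -0.48 over 8 genes (percentile 1.37), with GATA3 3.85-fold and MLPH 2.86-fold lower. Markers of other cell types were sparse. Among fibroblast and stroma markers, 4 of the 11 measured reached 50 counts. LUM was 15.0-fold higher, COL1A1 2.54-fold lower and COL6A3 5.52-fold lower with 9 resistant and 50 parental counts. The median of the 4 was -0.16 (percentile 52.0), which differed in sign from their mean of 0.30. It became 0.16 with the deposited FPKM values and 0.07 with the length trend removed. Among leukocyte markers 3 of 11 reached 50 counts, with a median of 0.74 (percentile 94.9) but a mean of -0.29. CORO1A was 6.79-fold higher and LYZ 19.5-fold lower. Among endothelial markers 2 of 7 did, with ESAM 3.02-fold lower, and among acinar and endocrine markers 2 of 9, with PRSS1 at 0.91 and PAX6 at -0.85. Of 10 cancer-testis genes in the table, 3 reached 50 counts, with a median of 0.75 (percentile 94.9). MAGEA12 had 199 and 0 counts, at least 66.8-fold higher, and PRAME was 4.41-fold lower.

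**Figure D3:**
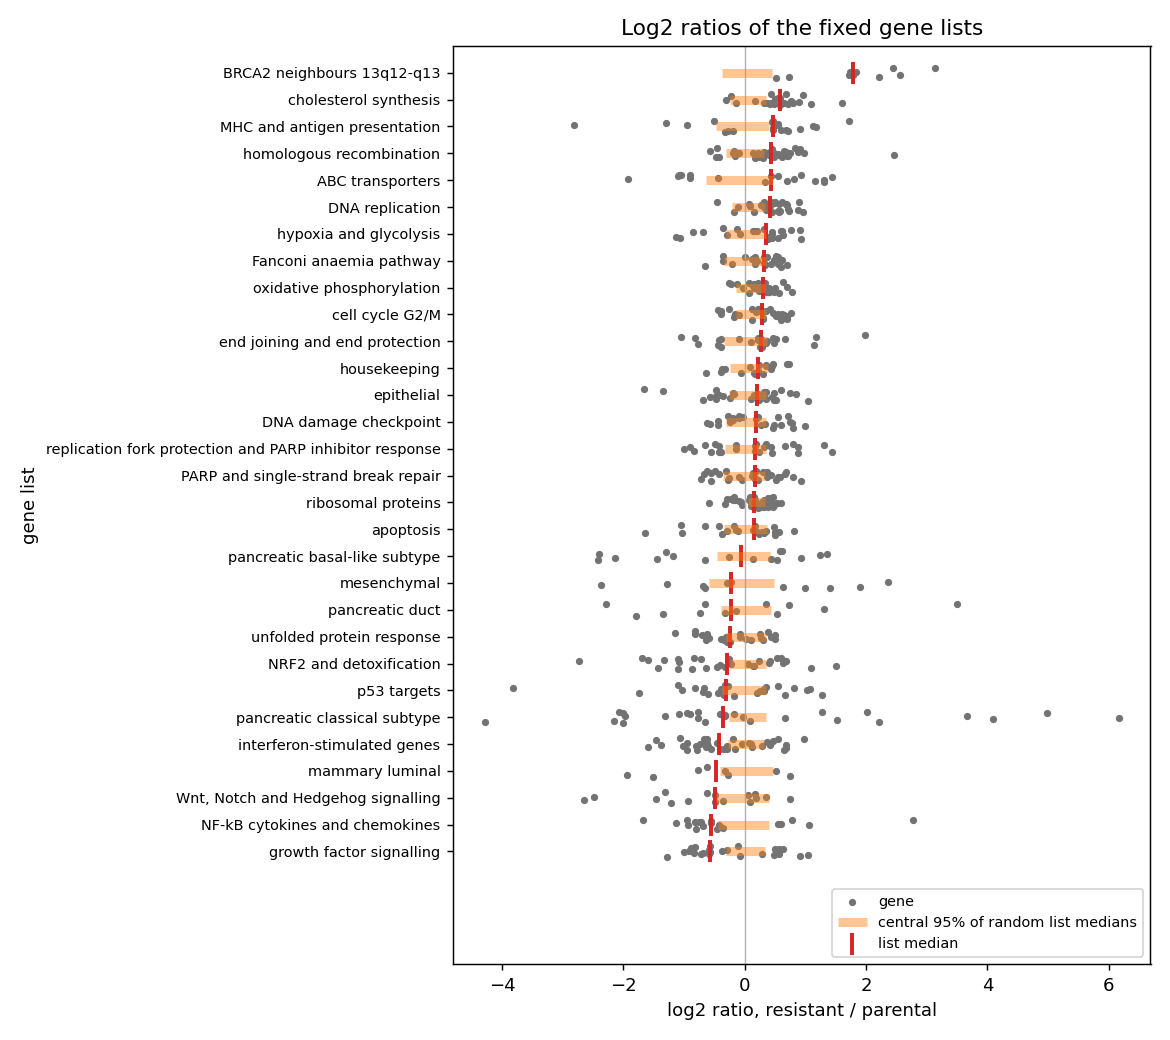
Log2 ratios of resistant over parental for members at 50 counts or more of each gene list fixed beforehand with at least 8 such members, with the list median in red and the central 95% of matched random list medians in orange. BRCA2 neighbours lie highest, at a median of 1.78, and growth factor genes lowest, at -0.58.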

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

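The deposited FPKM values, the removal of the length trend, protein-coding genes alone and the omission of chromosome 13 were chosen after seeing the data. BRCA2 stayed at a log2 ratio of 2.39 to 2.54 under 8 alternatives, and the median of the chromosome 13 block at 2.21 to 2.36 under 12. The neighbours' median ranged from 1.70 to 2.10, the lowest under median of ratios scaling (1.70), outside its resampling interval. That scaling moved the median of all genes by -0.08, and no scaling moved it by more than 0.1.

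The numbers of genes at least 2-fold higher and lower followed the count minimum and the size by construction. They were 1975 and 2821 with a minimum of 10 counts, 474 and 741 with 200 counts, 5565 and 5887 with no minimum, and 252 and 250 at 4-fold. Under the planned scaling alternatives they ranged from 796 and 1573 (median of ratios) to 1034 and 1184 (upper quartile), and the deposited FPKM values gave 842 and 995. All 906 and 1352 genes also had counting intervals that excluded equal levels, which the count minimum and the 2-fold size guarantee.

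The classical subtype list had a mean of 0.16 against a median of -0.36, since its higher members differ by more. Of the other list values, 397 stayed within their resampling interval and 6 moved outside it. Among 982 values of named genes other than BRCA2, 0 changed sign, 117 moved beyond the counting interval, and 39, from 23 genes, crossed the 2-fold size. With the length trend removed, the medians of 12 of 35 lists moved by over 1.5 times or changed sign, 10 of them toward 0. DNA damage checkpoint genes went from 0.18 to 0.09, epithelial genes from 0.20 to 0.11, apoptosis genes from 0.15 to 0.02, oxidative phosphorylation genes from 0.30 to 0.20, p53 targets from -0.30 to -0.19 and unfolded protein response genes from -0.24 to -0.15. Mesenchymal genes went from -0.22 to -0.37 and basal-like genes from -0.06 to -0.13. Ribosomal protein genes went from 0.15 to 0.09, and from percentile 20.3 to 2.99. The growth factor, Wnt and fibroblast lists make up the rest. The percentile of Fanconi anaemia genes went from 94.4 to 98.98, that of ABC transporters from 95.4 to 99.34 and that of Wnt, Notch and Hedgehog genes from 1.91 to 13.6. The cause was not tested.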

Other observations

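The tests of length and GC content and of copy gain in the chromosome 13 block, and both intestinal lists, were chosen after the result was seen. The other tests were set before their results. A bound was taken as met only when the 95% interval lay past it, a requirement applied after the first values were computed. It left open 2 explanations, admixed cells and unprocessed RNA, whose point values met the bounds set against them.

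Further stretches of neighbouring genes differed together. On chromosome 2, FAM110C to PLB1 had a median log2 ratio of -0.68 over 106 genes, and PPP1CB to VRK2, the next segment, one of 0.61 over 95 genes. The 96 genes from HYKK to TARS3 on chromosome 15 had a median of -0.67, with 26 at least 2-fold lower, and the 428 from UBP1 to PLS1 on chromosome 3 one of -0.50. A cluster of zinc finger genes from ZNF433 to ZNF442 on chromosome 19 had a median of -1.77, with 9 of 9 at least 2-fold lower, and the protocadherin genes PCDHB2 to PCDHB14 on chromosome 5 one of -2.53, with 6 of 6. Both clusters hold close paralogs that can share reads.

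All 8 intestinal genes that prompted a list, chosen for high ratios, were at least 2-fold higher. Members of the separate intestinal list differed in both directions. FABP2, a fatty acid binding protein gene, had 93 resistant and 0 parental counts, at least 31.2-fold higher. TFF3 and TM4SF5 were each 4.65-fold higher, CDHR5 4.23-fold and TM4SF20 34.5-fold, the last being among the genes that prompted a list. SLC5A1, a glucose transporter gene chosen after its value was seen, had a log2 ratio of -2.01.

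In the chromosome 13 block, of 1000 random gene orders, 0 reached the block's highest 21-gene median of 2.31, and the highest gave 0.79, which argues against a chance run. After the trends with length and GC content were removed, the block's median was 2.32 with 100% of its genes above 1. Its interval from resampling the block's genes was 2.21 to 2.51. Both trends were fitted on the other chromosomes. There the median ran only from 0.21 in the shortest to -0.37 in the longest of 10 gene groups. The Spearman correlation with GC content was -0.0513. Trends so small could hardly bring the block below 1, so this result was largely fixed in advance. It shows only that trends of that size do not account for the block. A copy gain may account for the block: the long non-coding genes LINC00543 and PAN3-AS1, which overlap no coding gene, had a median of 2.57. The 3 processed pseudogenes in the block had a median of 0.44, below that of the coding genes (EIF4A1P7 -0.17, CYP51A1P2 0.44, EEF1A1P3 1.14), although such copies can share reads with their parent genes. The series title names amplification of the mutant BRCA2 gene, which lies in this block, but no DNA was measured here. From RNA alone, so few genes leave a copy gain of the block open, and a shared change of transcription would look alike.

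CDX2, inside the block, was 7.23-fold higher, and VIL1, a brush border gene outside it, had 2719 resistant and 170 parental counts. CDX2 and VIL1 were chosen after their values were seen, so neither is evidence for a programme. The 8 intestinal genes that prompted a list were chosen for high ratios, so their median of 5.03 is no evidence. A separate intestinal list had a median of 1.55 over 14 genes (resampling interval -0.23 to 2.03) at percentile 100, with 8 at least 2-fold higher, 1 at least 2-fold lower and 4 below 0. The percentile met the bound set for a CDX2-linked programme. That list was also written after the data were examined, and admixed intestinal cells could give the same percentile. The percentile therefore does not show that CDX2 drives such a programme. Cells of an intestinal line in the resistant culture were left open. Of the 14 members at 50 counts or more, 7.14% (exact binomial interval 0.181 to 33.9) were at 3 counts or fewer in the parental library. That interval treats the genes as independent draws, which listed genes need not be. The point value met the bound set against admixed cells, but its interval did not, and so few genes cannot decide. The median parental count of those 14 was 324.5.

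Long genes were lower in the resistant library, with a median log2 ratio of 0.21 in the shortest of 10 equal groups of coding genes and -0.37 in the longest. Across 11933 genes, which are not independent replicates, the Spearman correlation with length given GC content was -0.157 (interval -0.174 to -0.139), which argues against GC content. With genomic span given exonic length it was -0.0365 (interval -0.0548 to -0.0179). The interval lay wholly short of the value predicted for less unprocessed RNA. It also crossed the bound set against that explanation, so a contribution stays open. RNA integrity and library batch were not given, and no biological explanation was tested.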
